A study of Homo sapiens with 3 samples.

How the data were processed

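A pooled CRISPR knockout screen was read out by sequencing the guide cassettes in genomic DNA of Ishikawa cells, an established human endometrial cancer cell line. Per the labels, 100000000 cells received library B of the human GeCKO v2 collection at a multiplicity of infection of 0.3, and puromycin selection lasted 48 h. There were 3 libraries, 1 per group. The baseline library was collected at day 0, the control library after 10 days in DMSO, the solvent, and the MPA library after 10 days in 15 μM MPA, a synthetic progestin that the labels name medroxyprogesterone. Per the labels' protocols, the cassettes were amplified in a first PCR of 18 to 22 cycles and a second of 8 to 12 cycles, and read as 150 bp paired ends.

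The deposited raw counts are whole reads per guide, with no normalization. How reads were matched to guides is not given in the sources used here. The deposited normalized counts, treated as a signal, equal the raw counts times 1 constant per library, which was 1.12 for baseline, 0.941 for control and 0.959 for MPA. The method behind these constants is not given in the sources used here. The authors' gene table gives, per the file headers, a beta per gene for control and for MPA, with z, p-values and FDR. Each beta was set against the baseline, and on the values it behaved as a natural log ratio, with a slope of 0.938 for control and 0.967 for MPA on the mean natural log ratio of the deposited normalized counts. The z value is a score made by the authors' fit, whose tool is not given in the sources used here. A deposited summary of summed counts per gene was not used here.

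Guides with a mean raw count of at least 30 over the 3 libraries were kept, which left 56741 of 56869. Counts were scaled by median-of-ratios factors over the kept guides, of 1.04 for baseline, 0.999 for control and 0.975 for MPA. The log2 fold change of a guide was taken with a pseudocount of 1, and the gene score is the median over the kept guides. Genes with at least 3 kept guides were scored, 18262 of 18834. A gene was called enriched at a score of at least 1 with every guide above 0, and depleted at a score of at most -1 with every guide below 0. With 1 library per group no residual spread can be estimated, so edgeR was not used, no p-value was computed, and no difference has a replicate check.

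Counts of called genes were set beside 100 random reassignments of guides to genes and beside 10000 pseudo-genes, each of 3 non-targeting guides. Overlaps were set beside 100 reassignments that moved each guide with its values in all 3 comparisons. The median score of each of 26 gene lists was placed among 10000 random lists of the same size, matched on deciles of mean count. A list stood apart below percentile 0.5 or above 99.5, as a description of these libraries. Intervals on ratios of summed counts are exact 95% Clopper-Pearson intervals. They cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

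The rules, the lists and the alternatives were fixed before the data were examined. The rule for named genes took the 12 highest and 12 lowest scores in MPA vs control, and the 6 highest and 6 lowest in each other comparison, among genes whose guides all moved the same way. It added up to 4 members per list with the largest absolute score in MPA vs control, then PGR, ESR1, NR3C1 and further fixed genes that are not reported here, and the top 5 genes of each side in the authors' deposited table. Alternatives were 3 other scalings, 2 other count minimums, 2 other pseudocounts, the mean of guides, a minimum of 2 guides, 2 other size rules and leaving out each guide of a named gene. A correction for guide GC content and thinning to equal totals were added after seeing the data. For values without a binomial interval, a move within 1 bootstrap SD over genes or guides was taken as no move, a measure that replaced fixed tolerances after a first round had been seen.

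The scoring was tested on simulated counts of the real guides with 200 changed genes. In the MPA vs control simulation, 95.8% of 48 genes lowered to a fold of 0.4 and 100.0% of 50 genes raised to a fold of 2.5 were called, with 0 of 18061 unchanged genes called. Every guide of a changed gene was given the same fold. These shares therefore do not cover genes whose guides differ in effect, as those of DUX2 and WRN did here. Symbols are those of the deposited tables. Of the 18834 targeted symbols, 17311 are current in the RefSeq annotation of GRCh38.p14, 1409 are older synonyms and 114 matched neither. That annotation served only for names and gene order, and no coordinates are printed because the sources used here name no build. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.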

Results

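The screen counted 56869 guides, of which 1000 were non-targeting, in 3 libraries of Ishikawa endometrial cancer cells. Each group had 1 library, so no value below has a replicate error. The libraries held 22527777 counts at baseline, 22556693 in control and 23162120 in MPA. The median count per guide was 369, 366 and 378 in that order, and 4, 6 and 5 guides had a count of 0. The Gini index, which is 0 for a perfectly even library, was 0.298, 0.310 and 0.298. The log2 fold changes of the 997 kept non-targeting guides had an SD of 0.23 in MPA vs control, beside 0.11 from counting alone. Their SD was 0.21 in control vs baseline and 0.20 in MPA vs baseline.

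The control and baseline libraries show which knockouts were lost over 10 days of growth without the progestin. Guides against ribosomal protein genes were the most reduced of the 26 lists, with a median gene score of -0.91 over 69 genes, 18 of them depleted. RPL13, a protein of the large ribosomal subunit, fell by 2.61 on the log2 scale. DNA replication and cell division genes had a median of -0.70, with 18 of 52 depleted, among them GINS1, a subunit of the replicative helicase complex, at -1.66. Proteasome genes had a median of -0.55, with 10 of 31 depleted, such as PSMD8 at -2.23. Spliceosome genes had a median of -0.49, with 5 of 40 depleted, such as BUD31 at -2.36.

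Over all genes, 209 of 18262 were depleted and 0 were enriched in control vs baseline. Reassigned guides gave a mean of 25.5 depleted genes and at most 37. Scaling by non-targeting guides gave 382 depleted genes and the authors' normalized counts gave 396. The lowest scores among genes whose guides all moved the same way were DUX2 at -4.51, INO80C at -3.66, LOC100507462 at -3.42, ST20 at -3.23, WRN at -3.23 and NPM1 at -3.09. INO80C belongs to a chromatin remodelling complex, WRN is a RecQ helicase, and NPM1 is a nucleolar protein. Their guides differed widely, from -5.08 to -0.08 for DUX2 and from -3.29 to -0.13 for WRN. The highest scores among such genes, none past the size rule, were C5orf47 at 0.94, DCP1B at 0.90, LOC100127983 at 0.77, DNAAF1 at 0.71, CATSPERB at 0.68 and HERC5 at 0.67.

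Further lists stood below the random lists in control vs baseline. The RNA polymerase and transcription list had a median of -0.16 at percentile 0.28, with 5 of 36 genes depleted, such as POLR2C at -2.12. Mediator and cohesin genes had a median of -0.20 at percentile 0.04, with 2 of 36 depleted. Respiratory chain genes had a median of -0.13 at percentile 0.30, with 0 of 42 depleted. With a count minimum of 100 these 3 lists lay at percentiles 4.3, 0.59 and 2.27, inside the range of random lists. Respiratory chain genes also lay inside it with no count minimum and with a minimum of 2 guides.

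In MPA vs baseline, the same question asked of the treated culture, 87 genes were depleted and 0 were enriched. Reassigned guides gave a mean of 6.31 depleted genes and at most 11, and the authors' normalized counts gave 141 depleted genes. Ribosomal protein genes had a median of -0.55, with 7 of 69 depleted, and RPL13 fell by 1.17 on the log2 scale. Proteasome genes had a median of -0.40 with 7 of 31 depleted, DNA replication and cell division genes -0.34 with 7 of 52, and spliceosome genes -0.30 with 3 of 40. Among genes whose guides all moved the same way, the lowest scores were ZNF573 at -4.25, DUX2 at -3.50, ST20 at -3.45, LOC100507462 at -3.32, UPP2 at -2.27 and NSF at -2.23. NSF is an ATPase of membrane fusion. The highest among such genes, none past the size rule, were SCARA3 at 0.82, COLEC12 at 0.72, PSME4 at 0.66, DCP1B at 0.65, SEC63 at 0.64 and CASP6 at 0.62.

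The RNA polymerase list stood below the random lists in MPA vs baseline too, with a median of -0.14 and 1 of 36 genes depleted. Respiratory chain genes had a median of -0.11 at percentile 0.32, with 0 of 42 depleted, but lay inside the range of random lists in 4 settings: no count minimum, a minimum of 2 guides, GC correction and thinned libraries, at percentiles 0.72, 0.60, 0.78 and 0.90. Of the genes depleted in either culture, 72 were depleted in both, 137 in control alone and 15 in MPA alone. Independent lists would share 1.0 gene, and reassigned guides that kept their values in both comparisons shared a mean of 3.97 and at most 12. Part of the excess over independent lists may come from the shared baseline, which the reassigned guides also carried. Across the 55744 targeting guides, the fold changes of both cultures against baseline had Pearson's r of 0.789, Spearman's rho of 0.663 and a covariance of 0.127. Non-targeting guides had r of 0.390 and a covariance of 0.0164. A Poisson simulation of unchanged guides, which holds counting error only, had r of 0.506 and a covariance of 0.00766. The covariance of targeting guides exceeded that of non-targeting guides by 0.111. Guides are not independent replicates.

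**Figure D1:**
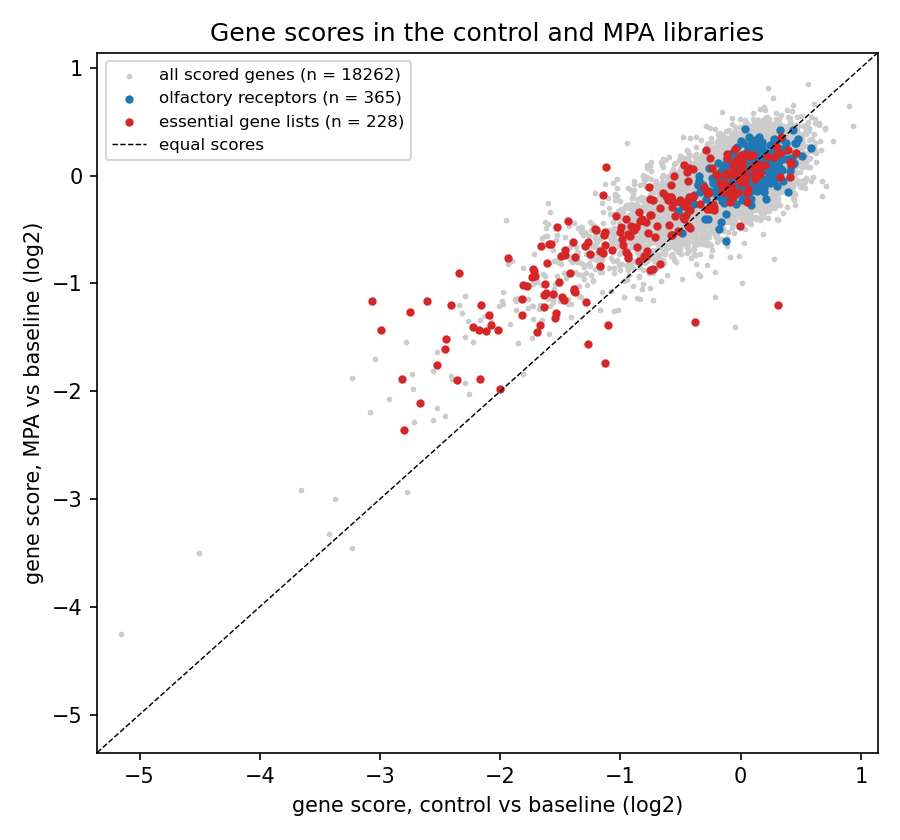
Gene scores (log2) in control vs baseline, on the horizontal axis, and MPA vs baseline, on the vertical axis, for 18262 genes, with 228 essential list genes in red and 365 olfactory receptors in blue. Essential list genes have a median of -0.60 in control and -0.37 in MPA, and most of the strongly reduced ones lie above the dashed line of equal scores.

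The direct comparison of MPA with control asks which knockouts fared differently under the progestin. The score was at least 1 with every guide above 0 for 8 genes. ATP6V0C, a subunit of the vacuolar proton pump, had a score of 1.62, and ATP6V1G1, another subunit, had 1.31. RPL13 had 1.44, GOLGA6L1 1.24, and the splicing-related genes GPKOW, SART3, SRSF2 and SNRNP25 had 1.11, 1.10, 1.08 and 1.04. No gene was depleted, beside a mean of 0.05 from reassigned guides. Enriched genes numbered 15 under scaling by non-targeting guides and 14 with the authors' normalized counts, and the mean of guides kept 5 of the 8.

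Reassigned guides gave a mean of 1.13 enriched genes and at most 4. All 8 enriched genes were also depleted in control vs baseline, where independent lists would share 0.092 genes. Both comparisons use the control library, and among the enriched genes that reassigned guides gave, 60.5% were depleted in control vs baseline too. The ratio of summed counts in MPA over control was 2.86 for ATP6V0C, with a 95% interval of 2.49 to 3.30, and 2.56 for ATP6V1G1, with 2.20 to 2.99. With any 1 guide left out, ATP6V0C, ATP6V1G1 and RPL13 stayed at 1.02 or above. The lowest such score was 0.92 for SART3, 0.71 for GOLGA6L1, 0.69 for SRSF2, 0.68 for GPKOW and 0.59 for SNRNP25.

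The 3 guides of ATP6V1G1 had log2 fold changes of 1.31 (CCATCCTCCAGACATACTTC), 1.54 (TGAAAACAGGAAAGAACCGG) and 1.24 (GCAGGCCAAAGAAGAAGCTC). Those of ATP6V0C had 1.62 (CCTGATTCTCATCTTCGCCG), 3.63 (GCGCTCACCGCTGAAGACCA) and 0.78 (ACCGCTCTTGGCTGTGCCAT). The guide at 3.63 had 575 counts at baseline, 20 in control and 265 in MPA. Among genes whose guides all moved the same way, the next highest did not pass the size rule: POLR2J at 0.99, NSA2 at 0.97, TINF2 at 0.96 and PRC1 at 0.96. The lowest scores among such genes, also short of the rule, were DNAAF1 at -0.86, GCSAML at -0.80, CEP290 at -0.78, CACNA1D at -0.73, FIBIN at -0.67 and TMUB2 at -0.66. TRIM10 followed at -0.64, SRD5A1, a steroid 5-alpha-reductase, at -0.59, OR52B6 at -0.58, PDE4B and GRIK2 at -0.57 and FAM126B at -0.56.

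**Figure D2:**
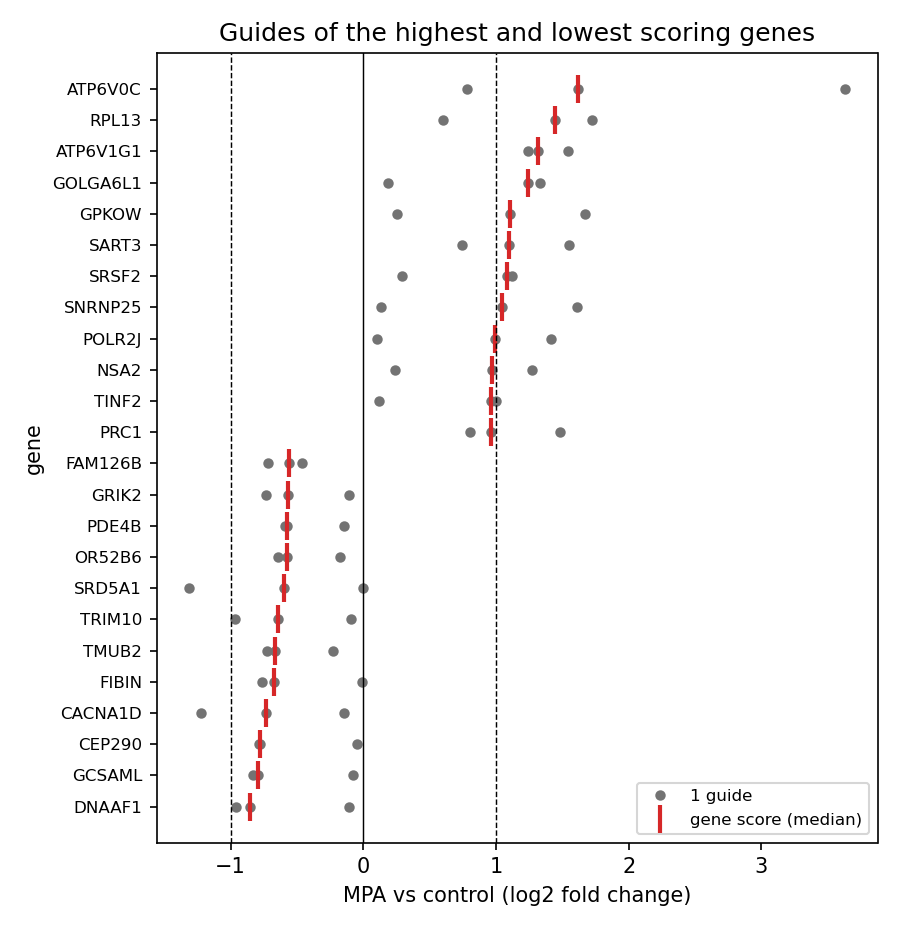
Log2 fold changes in MPA vs control of each guide (grey dots) and the gene score, the median of 3 guides (red bars), for the 12 highest and 12 lowest scoring genes whose guides all moved the same way. The dashed lines mark the size rule at -1 and 1, which 8 genes passed upward and 0 downward.

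Of the 26 lists, 5 stood above the random lists in MPA vs control. Ribosomal protein genes had a median of 0.36, with 63 of 69 scores above 0, and DNA replication and cell division genes had 0.31, with 42 of 52 above 0. The RNA polymerase list had a median of 0.16, the spliceosome list 0.14 and the Mediator and cohesin list 0.14. Of the members of these 5 lists, RPL13 alone passed the size rule. MAD2L1, a spindle checkpoint gene, had a score of 1.90 but 1 guide at -0.18, and so was not called. Proteasome genes had a median of 0.14 at percentile 98.9, inside the range of random lists. Mediator and cohesin genes lay inside it at a count minimum of 100, at percentile 99.3, and spliceosome genes with thinned libraries, at percentile 99.4.

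The 228 essential genes, which are the ribosomal, proteasome, spliceosome, DNA replication and RNA polymerase lists together, had a median score of -0.60 in control vs baseline, -0.37 in MPA vs baseline and 0.25 in MPA vs control. The 365 olfactory receptors, taken as genes these cells do not need, had 0.09, 0.06 and -0.04. Under scaling by non-targeting guides the olfactory medians changed sign, to -0.09, -0.06 and 0.04. The difference between the groups in MPA vs control was again 0.29, which scaling could not alter, since it shifts all guides of a comparison almost equally. The chance that an essential gene scored below an olfactory receptor was 0.864 in control and 0.817 in MPA. An essential gene scored above an olfactory receptor in MPA vs control with a chance of 0.815. Guides of the same gene had an intraclass correlation of 0.0783 in MPA vs control, 0.209 in control vs baseline and 0.172 in MPA vs baseline, beside at most 0.0117 with reassigned guides.

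The hormone-related lists stayed inside the range of random lists in MPA vs control. Steroid receptors and their chaperones had a median of -0.01, with 0 of 20 called. PGR, the progesterone receptor, had a score of 0.13 with guides from -0.45 to 0.27, ESR1 had -0.14 and NR3C1 -0.04. HSPA8, a chaperone, had 0.69, beside -0.61 in control vs baseline and -0.04 in MPA vs baseline. Receptor coregulators had a median of 0.07, with CREBBP at 0.46 and MED1 at 0.45. In control vs baseline CREBBP had -0.38 and MED1 -0.99, beside 0.17 and -0.54 in MPA vs baseline. Progestin response genes had a median of 0.03, with STAT5A at 0.26 and HSD17B2 at -0.24. Steroid metabolism and drug transport genes had a median of -0.08 at percentile 0.51, next to the limit of 0.5.

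Growth and tumour lists also stayed inside that range, with 0 genes called in each. PI3K, AKT and mTOR genes had a median of 0.02, with DEPDC5 at 0.44 and MTOR at 0.43. MTOR was called depleted in control vs baseline, at -1.04, and had -0.61 in MPA vs baseline. DEPDC5 had -0.20 and 0.31 there. Endometrial cancer drivers had -0.01, with SOX17 at 0.60. Homologous recombination and Fanconi genes had 0.13, exactly on the upper limit, with BRCA1 at 0.73. Wnt genes had -0.06, RAS and MAPK genes -0.05, Hippo genes -0.01, TGF-beta and BMP genes 0.03, apoptosis genes 0.00, and mismatch repair genes 0.02. Cholesterol synthesis genes had 0.01, SWI/SNF genes 0.01, Polycomb and histone methylation genes 0.01, and respiratory chain genes 0.02. The oxidative stress and ferroptosis list had -0.02, with GPX4, a lipid peroxide reductase, at -0.55 and guides from -1.63 to 0.36. With 1 guide left out that score ran from -1.09 to -0.09. GPX4 had -0.05 in control vs baseline and -1.40 in MPA vs baseline, where it was not called.

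**Figure D3:**
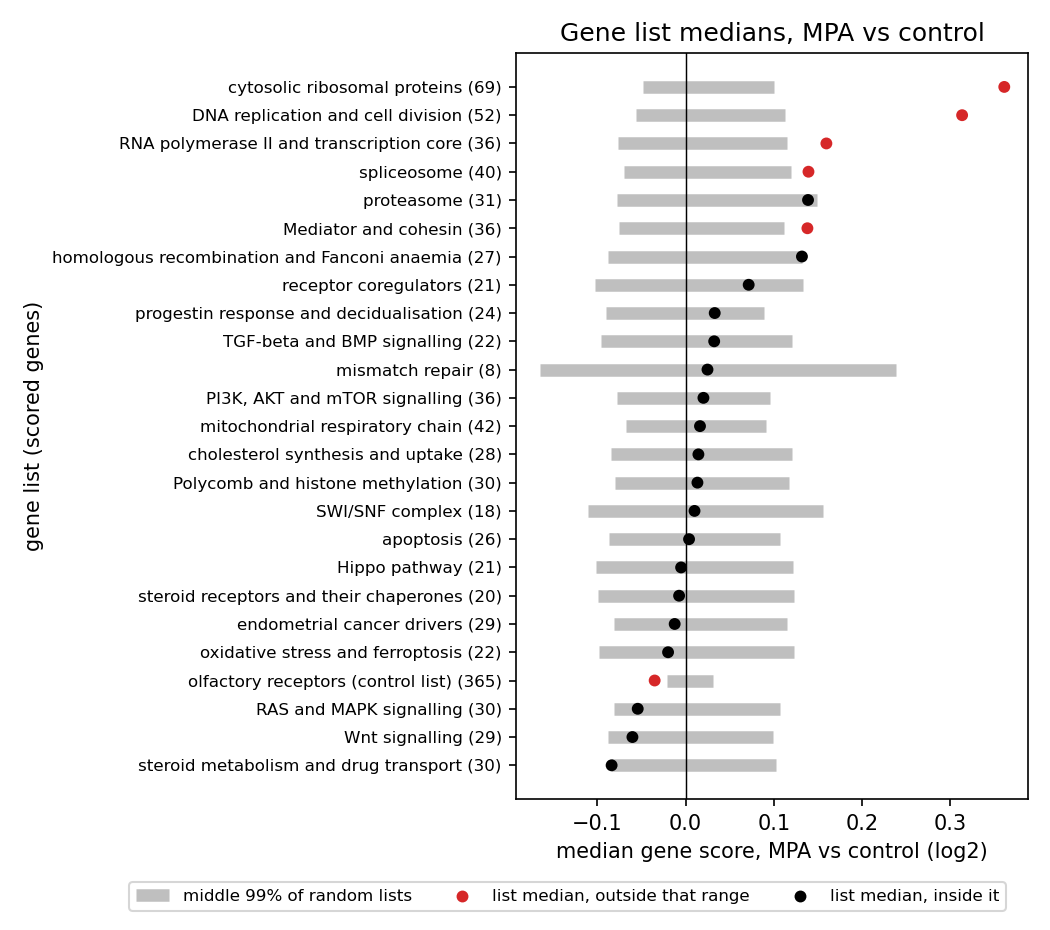
Median gene score (log2) in MPA vs control of the gene lists, with the number of scored genes in brackets, and the middle 99% of random lists of the same size as grey bars. Of the lists, 5 lie above their bars (red dots), led by ribosomal proteins at 0.36, and the olfactory receptors lie below theirs at -0.04.

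The authors' deposited table compares each culture with the baseline. It lists 66 genes at an FDR under 0.05 in control, 61 of them with a negative beta, and 54 in MPA, 48 of them negative, with 41 genes in both. By the Wald FDR in the authors' deposited table, 0 genes lie under 0.05 in either condition. The negative side in MPA is led by ST20-MTHFS, DUX2, ST20, ZNF573 and NUDT21, and the positive side by BMX, TXNDC8, C18orf54, OSBPL8 and NDUFC2, per the authors' deposited table. These positive betas against baseline ran from 0.316 for C18orf54 to 0.364 for BMX. BMX had a higher beta in control, 0.398, and the others a lower one than in MPA. The difference of the authors' betas between MPA and control had Spearman's rho of 0.865 with the gene scores in MPA vs control, across genes, which are not independent replicates. Of the 12 genes with the highest difference, 5 were among the 12 with the highest scores.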

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

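The named genes below had scores of opposite sign in control vs baseline and MPA vs baseline, under the main scaling and under scaling by non-targeting guides. With 1 library per culture the difference was not tested, and 7.69% of all 18262 scored genes met the same condition, beside 19.0% of the 153 named genes, many of which were chosen for their score in MPA vs control.

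Lower in MPA than in control, by the score in MPA vs control, were DNAAF1 at -0.86, GCSAML at -0.80, CEP290 at -0.78, CACNA1D at -0.73, TMUB2 at -0.66, SRD5A1 at -0.59, PDE4B at -0.57, GRIK2 at -0.57 and FAM126B at -0.56. WWC1 at -0.52, OR5AP2 at -0.46, OR5H15 at -0.45, DNMT1 at -0.39, ABCC2 at -0.35 and CATSPERB at -0.34 followed. None of these reached the size rule.

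Higher in MPA than in control, by the same score, were BRCA1 at 0.73, DIABLO at 0.55, PSMA4 at 0.52, HMGCS1 at 0.50, CREBBP at 0.46, DEPDC5 at 0.44, PTPN14 at 0.44, DNAJA1 at 0.35, SHOC2 at 0.27, NCOR1 at 0.27, BMPR1A at 0.26, FOXA2 at 0.25 and FOXO3 at 0.19. PGR had 0.13, although its median lay at 0.20 in control and -0.21 in MPA, since a different guide gave the median in each comparison. None of these reached the size rule either. With 1 guide left out the score in MPA vs control reached -0.12 for DNAJA1, -0.03 for SHOC2 and -0.16 for PGR, and the interval of the summed count ratio held 1 for these 3 and for CREBBP. The signs against baseline that flagged these genes were less stable with 1 guide left out. CREBBP, DEPDC5, NCOR1 and PSMA4 lost theirs in control. BMPR1A, FOXA2, FOXO3, CATSPERB, DNMT1, OR5H15 and PDE4B lost theirs in MPA, and DNAJA1, HMGCS1 and PGR in both. PTPN14, SHOC2, SRD5A1, TMUB2 and WWC1 are not sorted here. With all guides, WWC1 and TMUB2 lay at only -0.02 and -0.04 in MPA vs baseline. BRCA1, DIABLO, ABCC2, CACNA1D, CEP290, DNAAF1, FAM126B, GCSAML, GRIK2 and OR5AP2 kept both signs under the main scaling. Guides were not left out under scaling by non-targeting guides, which lowers the median score by 0.19 in control and 0.11 in MPA. The lowest score with 1 guide left out was smaller than that shift for ABCC2, CACNA1D, FAM126B, GRIK2 and OR5AP2 in control and for BRCA1 and DIABLO in MPA. CEP290 had only 0.0006 in control under that scaling with all guides. DNAAF1 and GCSAML exceeded the shift.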

How the results depend on the processing

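The GC correction and the thinning were chosen after seeing the data. In all settings but the size rules, 0 genes were depleted in MPA vs control and 0 enriched against baseline. Enriched genes in MPA vs control numbered 15 under scaling by non-targeting guides and 14 with the authors' normalized counts, each with all 8 main genes. Depleted genes in control vs baseline numbered 382 and 396 under those scalings, and with the authors' normalized counts 141 in MPA vs baseline, again with all main genes. These scalings lower the median of all gene scores by 0.19 and 0.20 in control vs baseline and by 0.11 and 0.13 in MPA vs baseline. At a size of 0.5, enriched and depleted genes numbered 183 and 19 in MPA vs control, 47 and 707 in control vs baseline, and 22 and 400 in MPA vs baseline. Reassigned guides gave means of 58.4 and 10.0, 33.1 and 299, and 14.8 and 134 in that order, and reached 49 and 25 for the 47 and 22 enriched genes, which lie within chance. At that size 1.84% of pseudo-genes of non-targeting guides counted as enriched in control vs baseline, beside 0.257% of genes. That share reflects the non-targeting median of 0.20 there, since 6 of 10000 pseudo-genes counted once centred on it. At a size of 1 the pseudo-genes gave 0 in every comparison. At a size of 2 the 8 enriched genes became 0, and depleted genes numbered 39 in control and 10 in MPA vs baseline. With a pseudocount of 10, 6 of the 8 enriched genes stayed enriched, and with the mean of guides 5 of the 8. Essential minus olfactory medians were then -0.95 in control and -0.61 in MPA vs baseline, with chances of an essential gene scoring lower of 0.930, 0.897 and, in MPA vs control, 0.137. The cause was not tested. At a count minimum of 100, guide agreement was 0.0856 in MPA vs control and 0.162 in MPA vs baseline. The shared baseline correlation was 0.784 after GC correction. Kept guides had a Gini index of 0.296 at baseline, 0.308 in control and 0.297 in MPA, as low guides were removed. List medians were recomputed only where they stood apart in the main setting, and for a few further lists. Of these, 352 values kept their side of the limits and 11 fell inside it. The other medians were not checked, among them steroid metabolism and homologous recombination in MPA vs control, which lay at the limits. Of the named gene scores, 1272 values moved beyond their counting interval and 5022 did not. With any 1 guide left out, all 8 enriched named genes kept their sign, and 3 of 8 kept a size of 1. No paired analysis was possible because each group has 1 library. Depth was close to equal, and counting error was about equal to 0.11 or 0.12 per guide.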

Other observations

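The tests of scaling and of a common factor below were chosen after the results they bear on were seen, as were the larger number of random lists for gene families with near-identical copies, the test of neighbours gene by gene and the test of pump subunits beside lists with a like loss. Vacuolar proton pump subunits beyond ATP6V0C and ATP6V1G1 were read because those 2 were among the 8 enriched genes. In MPA vs control, ATP6V0D1 had a score of 0.90, ATP6AP1 0.68, ATP6V1E1 0.66 and ATP6V1B2 0.49. ATP6V0D1 and ATP6AP1 had -1.63 and -0.78 in control vs baseline, beside -0.56 and -0.03 in MPA vs baseline. The other subunits ranged from -0.18 for ATP6V0E1 to 0.32 for ATP6V0B and ATP6V1H.

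The 228 essential genes lost less in the MPA library than in the control library, by their median. A scaling error would move essential genes and olfactory receptors alike, but they differed by 0.289, outside the -0.04 to 0.04 of random lists. Guide GC content is argued against too, since 97.9% of the difference stayed after correction, with a 95% bootstrap interval of 96.9% to 103%. A culture that divided fewer times could give 1 common ratio of losses, which was 0.613 over all essential genes, and every list's interval held it, but the RNA polymerase list's ratio of 0.798 had an interval of 0.12 to 1.44, too wide to decide. That explanation stays open, as does a difference specific to the progestin, which 1 library per culture leaves untested.

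A set of 8 genes with scores from -5.15 to -2.22 in control vs baseline was picked after these were seen: DUX2, GOLGA6L1, NBPF9 and FOXD4L2, which by symbol belong to families with near-identical copies, and LOC100507462, ZNF573, NXNL2 and UPP2, with no evident reason, though NBPF9, ZNF573, NXNL2 and UPP2 each had a guide above 0 and were not called there. Guides that cut at several loci may be toxic whatever the gene does, which was weighed for the families alone. In 143 other genes of such families the median in control vs baseline was -0.05, at percentile 0.509 with a simulation error of 0.023, which does not separate it from the limit of 0.5 set in advance, and a first draw of 10000 lists had put it just under that limit. A copy-number gain of the segment would lower the neighbours too, whose median was -0.0827, but only 6 of 8 genes could be placed, which makes that test void for the set. Gene by gene, the neighbours' lower 95% bound stayed above -0.5 for DUX2, GOLGA6L1, ZNF573, NXNL2 and UPP2. DUX2 had 5 neighbours and the others 10. This argues against a gain there that lowers the neighbours' median to -0.5. A smaller gain, or a gain that misses most neighbours, was not tested. The neighbours of GOLGA6L1 had a median of -0.169 with an interval of -0.27 to -0.01, below 0. NBPF9, at -0.195 with an interval of -0.60 to -0.02, and the unplaced FOXD4L2 and LOC100507462 stay open.

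A candidate explanation for ATP6V0C and ATP6V1G1 is the common smaller loss of essential genes. Their mean of 1.47 lay at percentile 100 of pairs with a like loss in control, yet they were picked for their high scores, and reassigning the guides of all 240 such genes gave a top pair as high in 27.7% of draws, which does not decide it. The hypothesis of a shared property of the pump's subunits predicted that the 15 other subunits would also stand high after the common factor was taken off. Their median of 0.21 lay at percentile 100 of random lists, beyond 0.13, as the hypothesis predicted. Beside lists matched on the loss in control, their median score of 0.25 lay at percentile 99.97, beyond 0.19. These 15 thus scored higher than genes with a like median loss. No other gene list was put through either test. The RNA polymerase and the Mediator and cohesin lists had -0.16 and -0.20 in control vs baseline, beside 0.16 and 0.14 in MPA vs control. Hence the tests cannot tell a property of the pump from one shared with other essential genes. Both rest on 1 library per culture, and the common loss stays open, for ATP6V0C and ATP6V1G1 too.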
